A study of Zea mays with 12 samples.

How the data were processed

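Small RNA abundance per distinct sequence was measured by sequencing in 12 maize libraries, each a single library of its genotype and experiment. Per the labels, the 2007 shoot apex libraries followed the Lu et al. protocol, the 2011 shoot apex libraries a TruSeq kit and the ear libraries the Illumina small RNA v1.5 kit with barcodes, each with size selection of 10 to 40 nt. The authors deposited the values as RPM, reads scaled to the library total, and per the submitters' processing notes reads were matched with Novoalign 2.07.11 and B73 genome release 4a.53. The deposited tables mark each sequence as a perfect match to the B73 genome, to Mo17 shotgun clones or to both. Per the labels, a sequence was listed from 5 reads in the 2007 table (the label of Mo17xB73 does not state it) and from 1 RPM in the others. Further trimming settings are not given in the sources used here.

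The depth implied by the smallest RPM steps was 8636111 (B73), 6131790 (Mo17), 8526144 (B73xMo17) and 8538628 (Mo17xB73) reads in 2007, 34499678 (B73) and 34503424 (Mo17) in 2011, 4774757 (B73), 6410384 (Mo17) and 6146981 (B73xMo17) at high N, and 3840712, 6016372 and 5677392 in the same order at low N. With a tolerance of 0.1 reads, 100% of the low values were whole reads in 10 libraries. In the 2011 libraries only 67.7% (B73) and 68.5% (Mo17) were whole and the divisors differed by 0.0109%, so no reads were recovered for them. Per the labels both 2011 libraries carry the same barcode, so their implied depth may be that of 1 shared divisor. The tables list 95664, 85814, 118624 and 125712 sequences (2007, 2011, high N, low N). In all there were 348796 distinct sequences, of which 1892 were in all 4 tables and 8366 in the 3 with the hybrid.

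All contrasts were made within a table, because the tables were filtered and normalized separately. RPM were used as deposited. Shares were taken of the listed RPM of 18 to 26 nt and compared by exact two-sided sign-flip permutation over the experiments. Single-library shares and counts have 95% Clopper-Pearson intervals. These treat reads or sequences as independent and do not measure uncertainty about a genotype or a cross. For sequences, log2 ratios with 1 RPM added were formed in each table. limma with an intercept and a mean-variance trend was fitted over the 4 tables (inbreds) or the 3 with B73xMo17 (hybrid against the arithmetic mid-parent). Sequences needed at least 5 RPM in at least 1 of the compared libraries of each table. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Families were summed over sequences of 19 to 24 nt that hold bases 3 to 18 of a listed mature sequence, with a minimum of 10 RPM. Differences within 1 table were counted at 2-fold and 10 RPM. The sequences named in the text were the 3 largest mean ratios in each direction among the calls or, with no call, among sequences of one direction in all tables, and the most abundant 21-nt, 22-nt and 24-nt sequences. Tested families were named, and miR156, miR172, miR166, miR168 and miR399 were always given, while other families with values in 1 experiment were named after the values were seen.

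The design, its tests, thresholds, family lists and most alternatives were fixed before the data were examined. Chosen after were the correction for the first 3 bases, the removal of fragments of 5.8S and 18S rRNA starts, edgeR on recovered reads, the choice of sequences in the other experiment of the tissue, the 5 RPM minimum for one-genome sequences and their scaling by sequences of both genomes. edgeR quasi-likelihood tests with the table as a term used the tables with whole reads. They gave 9 (library totals) and 10 (TMM) calls between the inbreds and 54 and 51 between hybrid and geometric mid-parent. The minimum acts on the highest value of a sequence in its table (lowest such value 0.58 to 1.05 RPM), while single values go down to 1 read, so a 0 in a listed sequence was kept as 0.

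In the self-test, changes were added to simulated data with a dispersion of 0.05. For the inbred comparison, on 1865 sequences, limma recovered 52 of 100 sequences changed 2-fold and 89 of 100 changed 4-fold, with 4 false calls. For the hybrid comparison, on 8356 sequences, it recovered 18 of 100 changed 2-fold and 86 of 100 changed 4-fold, with 3 false calls. The simulated change was the same in every experiment, the dispersion was set and not estimated, and no 5 RPM minimum was used. These rates therefore do not give the power of the main tests on 88 and 360 sequences.

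The class-name columns of the low N table were only counted. Reads were not used here, and no genome was used, so sequences were not placed on chromosomes and the gene table of the reference was not used for coordinates. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.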

Results

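Small RNAs were sequenced from the maize inbred lines B73 and Mo17 and from their hybrids B73xMo17 and Mo17xB73, in which the seed parent is named first by convention. The 12 libraries came from 4 experiments. The 2007 shoot apex experiment held 4 libraries, 1 of each inbred and 1 of each reciprocal hybrid, from seedlings 11 days after sowing. The 2011 shoot apex experiment held 2 libraries, 1 of each inbred, from seedlings 14 days after sowing. The developing ear experiments, from field plots of 2009 with 200 kg of nitrogen per hectare (high N) or without added nitrogen (low N), held 3 libraries each: B73, Mo17 and B73xMo17. Every group was a single library, so a difference inside 1 experiment has no replicate check, and the tests use the experiments as replicates. The deposited values are RPM, the reads of a distinct sequence scaled to the library total. The implied library depth was 6131790 to 8636111 reads in 2007, 34499678 and 34503424 in 2011, 4774757 to 6410384 in the high N ears and 3840712 to 6016372 in the low N ears. The tables list only sequences above a minimum, and the listed sequences held between 7.89% (Mo17, 2007) and 31.1% (B73, 2011) of a library. Each listed sequence also matched the B73 genome or the Mo17 clones perfectly, with 0 that match neither. A Mo17 sequence missing from both therefore could not appear, and the size of this effect was not tested.

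The first comparison asked how the length classes of small RNA were made up. In plants the 24-nt class consists mainly of siRNAs that guide DNA methylation at repeats, the 21-nt class holds most microRNAs, and maize has in addition a large 22-nt siRNA class. The 24-nt class was the most abundant in all 12 libraries. In the 2007 shoot apex it made up 48.3% of the listed RPM of 18 to 26 nt in B73 (95% Clopper-Pearson interval 48.2 to 48.5%), 42.7% in Mo17, 44.3% in B73xMo17 and 44.9% in Mo17xB73. In 2011 it made up 40.1% in B73 and 42.5% in Mo17. In the ears it was between 60.2% (Mo17, high N) and 71.02% (Mo17 and B73xMo17, low N). The 21-nt class made up 18.9 to 28.1% in the shoot apices and 4.78 to 6.77% in the ears, and the 22-nt class 16.6 to 23.7% in the shoot apices and 10.5 to 15.6% in the ears. Tissue, year and library kit changed together, and the tables were filtered separately, so these levels across tables are given as values without a test. Counting intervals cover counting error only.

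**Figure D1:**
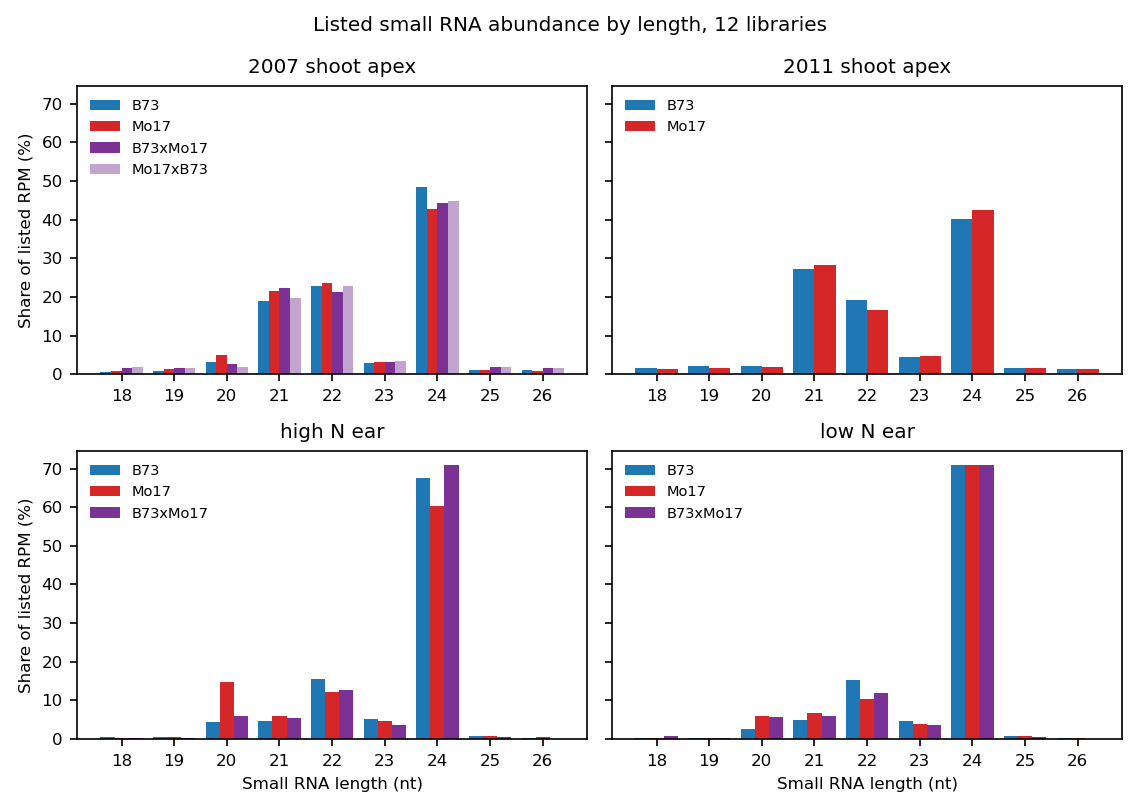
Share of the listed RPM (y axis, %) by small RNA length (x axis, nt) in 12 libraries, 1 panel per experiment and 1 bar per genotype. The 24-nt bar is the highest in each library and reaches 71.02% in the low N ears, and Mo17 in the high N ear has a 20-nt bar of 14.9%.

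The 21-nt share was lower in B73 than in Mo17 in 4 of 4 experiments, by −2.77, −0.79, −1.20 and −1.76 percentage points in the 2007 apex, 2011 apex, high N ear and low N ear (mean −1.63 ± 0.86, SD, n = 4, two-sided exact sign-flip permutation p = 0.125, the smallest that 4 pairs allow). The 22-nt share was higher in B73 in 3 of 4 experiments: 19.2 against 16.6% in 2011, 15.6 against 12.1% at high N and 15.3 against 10.5% at low N, but 22.9 against 23.7% in 2007 (mean difference 2.54 ± 2.41 points, SD, n = 4, exact permutation p = 0.25). The 24-nt share differed by 5.65 and 7.38 points in favour of B73 in 2007 and at high N, and by −2.35 and −0.22 points in 2011 and at low N (mean 2.61 ± 4.64, SD, n = 4, exact permutation p = 0.5). None of these differences can pass 0.05 with 4 pairs. Without fragments of the 5.8S and 18S rRNA starts, an alternative chosen after the data were seen, the mean was 0.43 points for 24 nt, 1.35 points for 22 nt and −1.92 points for 21 nt, so much of the 24-nt and 22-nt means lay with these fragments. For the hybrid B73xMo17 against the mean of its parents, the 22-nt share was lower in 3 of 3 experiments, by −1.98, −1.05 and −0.97 points (mean −1.33 ± 0.56, SD, n = 3, exact permutation p = 0.25, the smallest that 3 pairs allow). The 24-nt share stood at −1.25, 6.996 and 0.117 points from the mid-parent (mean 1.95 ± 4.42, SD, n = 3, exact permutation p = 0.75). Without the high N ear that mean was −0.57 points, and without the rRNA fragments 1.04 points.

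The most abundant 21-nt sequence was a microRNA in 11 of the 12 libraries, and rRNA fragments and sequences outside the fixed lists led the 22-nt and 24-nt classes. In the 2007 apex it was the miR166 sequence TCGGACCAGGCTTCATTCCCC in B73 (5683 RPM) and B73xMo17 (6999 RPM), and the miR168 sequence TCGCTTGGTGCAGATCGGGAC in Mo17 (4586 RPM) and Mo17xB73 (7344 RPM). In the 2011 apex it was the same miR166 sequence, with 56928 RPM in Mo17 and 56448 RPM in B73. In 5 of the 6 ear libraries it was the miR159 sequence TTTGGATTGAAGGGAGCTCTG, with 2324 RPM in B73 at high N and 4460 RPM in Mo17 at low N, while in B73xMo17 at low N it was ATAACTTGACGGATCGCACGG, with 1834 RPM. Among 22-nt sequences, a fragment of the start of 5.8S rRNA led in 3 of the 4 libraries of the 2007 apex (CACGACTCTCGGCAACGGATAT, 198.6 RPM in Mo17xB73), TCTAGGTCAAGAAAGTAGATGA led in Mo17 of 2007 (175.9 RPM, 0 in B73), and another 5.8S fragment led at high N (GACACGACTCTCGGCAACGGAT, 8200 RPM in B73 and 926.9 RPM in Mo17). GCCCCGCGTCGCACGGATTCGT led in 2011 with 1737 RPM in B73. The highest value at low N was that of CCTCTCTAAGAGAGGACGCGGC, with 584.6 RPM in B73xMo17 against 2.08 RPM in B73 and 1.83 RPM in Mo17. Among 24-nt sequences, AGAGAAGACTGTAAAGGACGGATA led in both 2007 inbreds (292.8 RPM in B73 and 229.9 RPM in Mo17), a 5.8S fragment in both 2007 hybrids (CACGACTCTCGGCAACGGATATCT, 383.9 RPM in Mo17xB73), and CAGCCCCGCGTCGCACGGATTCGT in 2011 (1299.5 RPM in Mo17). GATGTTGTTTTACATCACAGGCGG had the highest value in both ear tables: it had 904 RPM in Mo17 and 3.98 RPM in B73 at high N, and 2036 RPM in B73xMo17, 264 RPM in Mo17 and 115 RPM in B73 at low N. Fragments of the start of 18S rRNA summed to 24331 RPM (13.8% of the listed RPM) in Mo17 at high N against 6521 RPM in B73.

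The second comparison asked which sequences differed between the inbreds in every experiment. Of 88 sequences with at least 5 RPM in an inbred of each table, 11 differed by limma at a Benjamini-Hochberg adjusted p under 0.05: 6 were higher in B73 and 5 higher in Mo17, and all 11 had the same direction in 4 of 4 experiments. Of the 11, 8 were 22-nt, 2 were 21-nt and 1 was 24-nt. Of the 88 sequences, 42 were fragments of the rRNA starts and 8 matched microRNA families of the fixed lists, and the 11 were all among the other 38. limma had 12 sequences at an unadjusted p under 0.05, and edgeR on recovered reads called 9 with library totals and 10 with TMM scaling. The 3 largest means towards B73 were TTCAATGAGGACCAGAAGAAGC (mean log2 ratio 5.18, SE 0.73, limma adjusted p = 2.1e-05), with 18.99, 13.2, 30.8 and 215 RPM in the 4 B73 libraries and at most 0.12 RPM in Mo17, CAAGAAGGGTTCTGACAGCGG (4.94, SE 0.72, limma adjusted p = 2.6e-05) and TTCAAGGGACTTCAGCTTCGGC (4.30, SE 0.52, limma adjusted p = 5.0e-06). The 3 largest towards Mo17 were TTTCATTCGTCTGGCCAAGGGC (mean log2 ratio −4.44, SE 0.57, limma adjusted p = 6.6e-06), with 6.36, 49.8, 25.7 and 34.9 RPM in Mo17 and at most 0.61 RPM in B73, TGAGGTCGAGGACTATGATGAC (−3.68, SE 0.42, limma adjusted p = 3.7e-06) and CCAGGAAGCACGGACGATCTC (−3.63, SE 0.45, limma adjusted p = 5.0e-06). Ratios are on the log2(RPM + 1) scale, which understates the change of low sequences. The size of the p-values depended on the fit more than the number of calls did. The smallest limma adjusted p was 3.7e-06 in the main fit. It was 0.0026 without the mean-variance trend (10 calls) and 0.0014 with 5 RPM added (11 calls). The files mark 9 of the 11 as a perfect match to both genomes, the other 2 (CAAGAAGGGTTCTGACAGCGG and TGAACGAGAAAAGGCTGGAGAC) to B73 only. Of the 88 tested, 86 match both genomes and only these 2 match B73 only. In the 2007 hybrids TTCAATGAGGACCAGAAGAAGC had 8.21 RPM in B73xMo17 and 10.7 RPM in Mo17xB73, and TTTCATTCGTCTGGCCAAGGGC 2.93 and 3.40 RPM, between the inbreds. In the high N ear hybrid both stood above the higher inbred, with 71.6 RPM against 30.8 RPM in B73 and 35.3 RPM against 25.7 RPM in Mo17, while at low N both lay between the inbreds, with 40.3 RPM against 215 RPM in B73 and 17.8 RPM against 34.9 RPM in Mo17. The number of calls followed the minimum. With no minimum, 438 of 1865 sequences passed (226 higher in B73, 212 in Mo17), among them 225 of 546 22-nt sequences (41.2%), 61 of 169 21-nt sequences (36.1%) and 146 of 899 24-nt sequences (16.2%), while a minimum of 20 RPM left 1 call among 25. By genome match, with no minimum, 16.9% of 1688 sequences that match both genomes passed. The shares were 79.7% of 69 that match only B73 and 88.6% of 88 that match only Mo17.

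Within each experiment, sequences with at least 10 RPM in an inbred were counted as apart when they differed at least 2-fold. In the 2007 apex 51.1% of 658 sequences were apart (177 higher in B73, 159 in Mo17), in the 2011 apex 46.6% of 4208, in the high N ear 91.8% of 3266 and in the low N ear 81.4% of 3766. The 22-nt class had the highest share in both shoot apex tables, 65.2% in 2007 and 59.5% in 2011, against 37.4 and 44.2% in the 24-nt class. With a minimum of 50 RPM the 2007 share was 23.3%. Of the 136 sequences apart in 2007 and listed in 2011, 124 (91.2%) had the same direction in 2011, and 88 of them were 2-fold apart again with none 2-fold apart the other way. Of the 1921 sequences apart at high N and listed at low N, 1182 (61.5%) had the same direction, and 339 were 2-fold apart the other way. Read from low N to high N, 1812 of 2456 (73.8%) had the same direction and 282 were 2-fold apart the other way. In the high N ear the first 3 bases of a sequence accounted for 49.6% of the variance of the B73 to Mo17 log2 ratio among 24-nt sequences that match both genomes, against 7.33% in the low N ear, 3.75% in the 2007 apex and 0.39% in the 2011 apex. At high N, 24-nt sequences that start with GAC had a median log2 ratio of 1.97 and those that start with CGG one of −1.99. Ear values of single sequences below carry this limit.

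**Figure D2:**
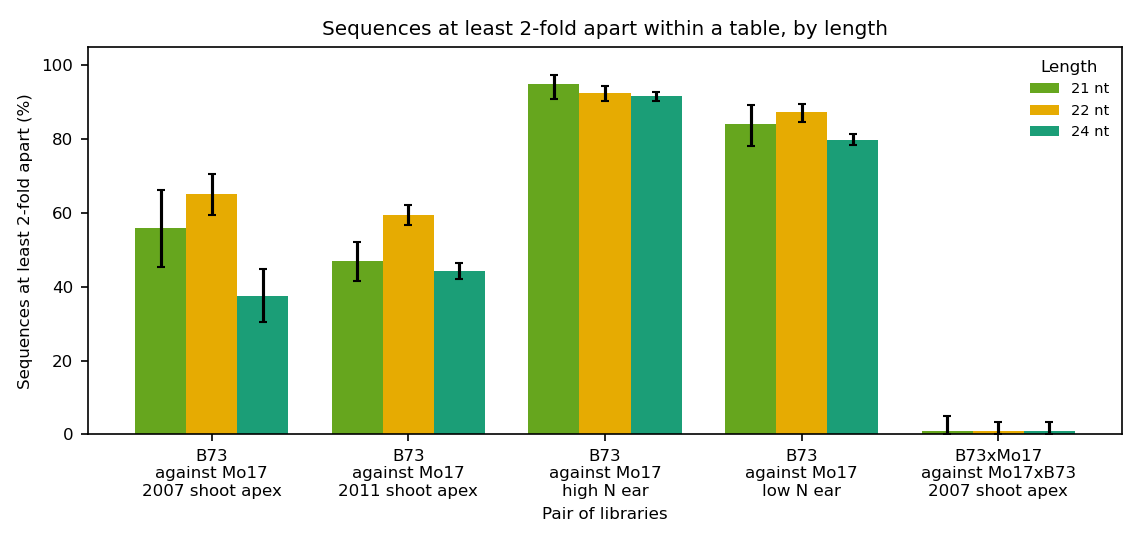
Percent of sequences at least 2-fold apart between 2 libraries of a table (y axis), by pair of libraries (x axis) and length, with 95% Clopper-Pearson intervals as error bars. The intervals treat sequences as independent and do not cover differences between libraries of the same genotype. The inbred pairs range from 37.4% (24 nt, 2007) to 94.9% (21 nt, high N ear), while the reciprocal hybrids stay at or below 0.91%.

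The reciprocal hybrids of 2007 address whether the direction of the cross matters. Of 699 sequences with at least 10 RPM in a hybrid, 8 (1.14%, 95% Clopper-Pearson interval 0.50 to 2.24%) were 2-fold apart, 1 higher in B73xMo17 and 7 higher in Mo17xB73. The interval treats sequences as independent and does not cover differences between libraries of the same cross. The share was 0.91% of 110 21-nt, 0.90% of 223 22-nt and 0.90% of 221 24-nt sequences. At 4-fold, none was apart. Of the 15 families with 10 RPM in a 2007 library, 0 were 2-fold apart between the reciprocals. The nearest was miR156, a regulator of the juvenile phase, with 2077 RPM in B73xMo17 and 1171 RPM in Mo17xB73.

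The files mark which sequences match the B73 genome or Mo17 shotgun clones perfectly. This mark does not settle which parent a sequence could come from, because both one-genome sets also had RPM in the other inbred. The highest such values were in 2007. There B73-only sequences had 11.6% of their B73 RPM in Mo17, and Mo17-only sequences 17.8% of their Mo17 RPM in B73. Between 70.1% (low N) and 78.9% (2007) of the listed sequences matched both. Sequences that match only B73 made up 8.96, 11.2, 20.45 and 21.2% of the listed RPM in the B73 libraries of 2007, 2011, high N and low N, and 1.14 to 2.35% in Mo17. Sequences that match only Mo17 made up 11.3, 10.8, 13.5 and 17.8% in the Mo17 libraries and 1.10 to 1.84% in B73. They were most frequent in the 24-nt class: at high N, B73-only sequences held 27.2% of the 24-nt RPM of B73 but 5.73% of its 22-nt RPM and 3.85% of its 21-nt RPM. In the hybrids both sets were present. B73-only sequences summed to 58.2% of their B73 level in B73xMo17 and 61.2% in Mo17xB73 in 2007, 39.3% at high N and 40.2% at low N. Mo17-only sequences summed to 97.7, 101.8, 58.9 and 42.0% of their Mo17 level. Both sums include sequences that also had RPM in the other inbred, so they are not levels inherited from 1 parent alone. With only sequences of at least 5 RPM in the inbred, a choice made after the data were seen, the 2007 values were 59.1 and 65.0% for B73-only and 59.9 and 66.4% for Mo17-only sequences. In the ears they were 19.5% at high N and 24.4% at low N for B73-only, and 44.6 and 21.3% for Mo17-only sequences. Values were also divided by the percent of the mid-parent held by sequences of both genomes, again after the data were seen. Without the minimum this gave 45.6, 44.4, 44.5 and 40.0% for B73-only and 76.6, 73.8, 66.7 and 41.8% for Mo17-only sequences. With the minimum it gave 46.0 and 49.9% for B73-only and 46.6 and 51.0% for Mo17-only sequences in the 2007 hybrids. In the ears it then gave 31.3 and 32.4% for B73-only and 71.8 and 28.3% for Mo17-only sequences.

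**Figure D3:**
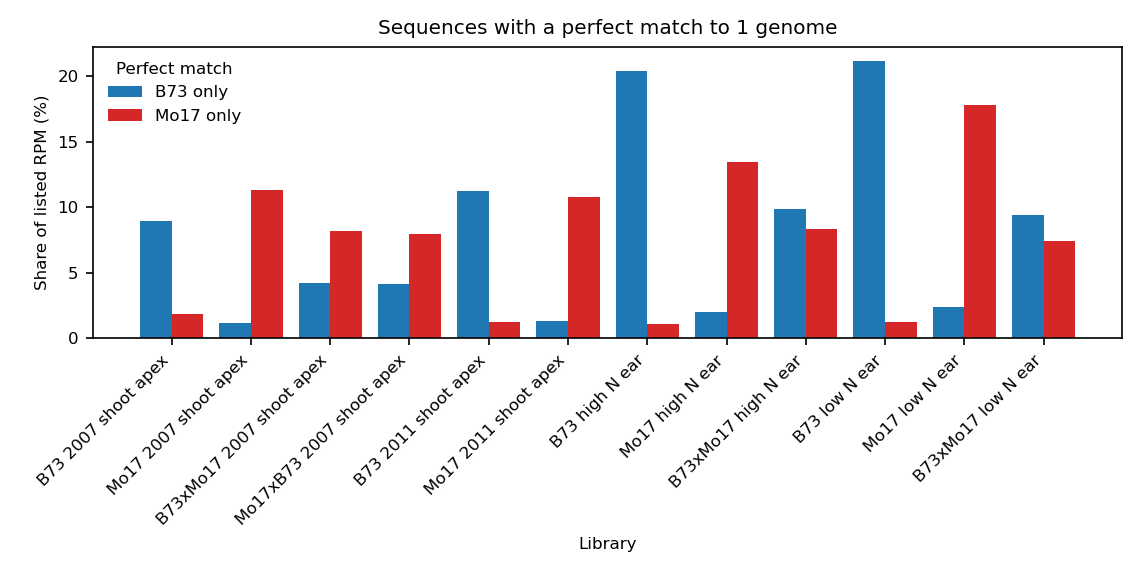
Share of the listed RPM of 18 to 26 nt (y axis, %) held by sequences that match only the B73 genome or only the Mo17 clones, per library (x axis). Each inbred carries its own set, 20.45% B73-only in B73 at high N for example, and every hybrid carries both sets at lower shares than the matching inbred.

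Sequences with at least 10 RPM in one inbred and listed at 0 in the other were followed into the hybrid. In the 2007 apex all 86 such B73 sequences and all 84 such Mo17 sequences were listed in both reciprocal hybrids (100% each; lower 95% Clopper-Pearson bounds 95.8 and 95.7%). In B73xMo17 their median level was 45.8% of the B73 value and 51.7% of the Mo17 value, and in Mo17xB73 49.4 and 58.8%. In the ears fewer were listed in the hybrid, 73.5% of 759 B73 sequences and 80.7% of 518 Mo17 sequences at high N, and 89.7% of 668 and 81.0% of 688 at low N. Their median levels there were 1.59, 5.86, 13.04 and 7.78% of the inbred value in the same order, while their summed RPM was 12.4, 32.7, 18.2 and 19.96% of that in the inbred. An extreme pair of single libraries chose these sequences, which tends to lower the hybrid percentage. The inbred ratios at high N also followed the first 3 bases, as given above. These levels therefore do not measure a loss in the hybrid. Among all sequences 2-fold apart between the inbreds, the hybrid lay between its parents for 90.2% of 336 in B73xMo17 and 86.3% in Mo17xB73 in 2007, for 75.4% of 2999 at high N and for 77.9% of 3065 at low N. Because an extreme inbred value selects the sequences, the hybrid was also placed for sequences chosen in the other experiment of the tissue, after the data were seen. In the experiment where the hybrid was read, these needed only unequal inbred values, not a 2-fold difference or 10 RPM. Of 421 such sequences in 2007, 191 were 2-fold apart in the same direction as in 2011 and 1 in the opposite direction. Inbreds that are nearly equal leave little room between them. The hybrid then lay between the parents for 60.6 and 57.5% in 2007, 40.8% at high N and 47.1% at low N. The rest lay mostly above the higher parent, 36.6 and 40.1% against 2.85 and 2.38% below the lower parent in 2007, 52.7 against 6.51% at high N and 33.2 against 19.7% at low N. A hybrid cannot lie below a parent listed at 0. A sequence under the minimum in both inbreds is listed only through a hybrid. Counts above and below were therefore not on equal terms. In the same-table count 9.24% lay above and 15.4% below at high N, and 3.36% above and 18.8% below at low N. The counts differ both in the experiment that chose the sequences and in the 2-fold gap, so the changed balance cannot be put down to either alone. The listed sequences that match both genomes summed to 127.6 and 137.9% of the mid-parent in the 2007 hybrids and to 88.4% at high N, and positions were not recounted without these shifts.

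Calls between B73xMo17 and the mid-parent across the 3 experiments with that hybrid depended on the tool and on the kind of mid-parent. Against the arithmetic mid-parent, limma called 0 of 360 sequences with at least 5 RPM in each table (smallest adjusted p = 0.985), with 10 at an unadjusted p under 0.05. edgeR on recovered reads called 54 with library totals and 51 with TMM scaling, all higher in the hybrid. A sequence entered when either inbred or the hybrid reached 5 RPM in each experiment, so a high hybrid value alone could bring it in. The edgeR mid-parent is the geometric mean of the inbreds by construction. That mean is never above the arithmetic one, so a hybrid at the arithmetic mean of unequal inbreds lies above it. In limma the median log2 ratio over the 360 sequences was 0.04 with the arithmetic and 0.34 with the geometric mid-parent. In edgeR it was 0.44 (library totals) and 0.39 (TMM). The edgeR calls therefore do not show levels above the arithmetic mid-parent. limma with a geometric mid-parent called 2, both higher in the hybrid. edgeR was not run with an arithmetic mid-parent, so the rest of the gap was not tested. With no limma call, the sequences of one direction in 3 of 3 experiments with the largest means are given. Above the mid-parent were CAAGAAGGGTTCTGACAGCGG (mean log2 ratio 1.98, SE 0.82), ACAAAAAGTTAAGCGAGCGTC (1.78, SE 0.76) and GATTTAATTAAATGGATCGACGGG (1.34, SE 0.63). Below it were GACTAAAGCGGTCAGACGGTGGAG (−2.26, SE 0.76), TGAGGTCGAGGACTATGATGAC (−2.14, SE 0.65) and ATCATGAAGATGATCGAAGTGG (−1.77, SE 0.72). The limma adjusted p of all 6 was 0.985.

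Of 28 microRNA and tasiRNA families in the fixed lists, 20 reached 10 RPM in at least 1 library. Between the inbreds, 4 families could be tested in all experiments, and none passed: miR168, which targets ARGONAUTE mRNA (mean log2 B73 to Mo17 ratio 0.64, SE 0.73), miR166, which targets HD-ZIP transcription factors of the meristem (0.18, SE 0.80), miR159, which targets MYB factors (0.13, SE 0.49), and miR319, which targets TCP factors (−0.32, SE 0.45). The limma adjusted p was 0.830 for all 4, with 0 at an unadjusted p under 0.05. Leaving out 1 experiment gave means from −0.20 to 1.13 for miR168 and from −0.58 to 1.05 for miR166, and a correction for the first 3 bases, chosen after the data were seen, 0.10 and −0.35, so neither sign was stable. The miR159 mean ranged from −0.11 to 0.48 when 1 experiment was left out, so its sign was not stable either. In the 2011 apex, where the labels give both libraries the same barcode, the inbreds were close, with 0 of 14 families 2-fold apart and a median log2 ratio of 0.03. There miR166 had 60870 RPM in B73 and 60515 RPM in Mo17, and miR156 61.1 and 57.7 RPM. In the 2007 apex 3 of 13 families were 2-fold apart, all higher in Mo17: miR827, which acts in phosphate supply (6.25 RPM in B73, 22.2 RPM in Mo17), miR164, which targets NAC factors (3.70 and 13.5 RPM), and miR169, which targets NF-Y factors (6.37 and 16.6 RPM). There miR156 had 2644 RPM in B73 and 4150 RPM in Mo17, miR172, which targets AP2-like factors, 71.5 and 96.0 RPM, and miR168 3509 and 4612 RPM. In the nutrient list, miR399, an indicator of phosphate supply, was at or below 3.65 RPM in all 12 libraries. miR395, miR397 and the phased siRNA triggers miR2118 and miR2275 had no listed member in any table.

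In the ears the inbred ratios of 6 families with 10 RPM at both nitrogen levels all had opposite signs at high and low N. miR166 had 799.5 RPM in B73 and 146.0 RPM in Mo17 at high N, and 109 and 593 RPM at low N. miR168 had 42.1 and 76.0 RPM at high N, and 475 and 52.9 RPM at low N. miR164 had 15.5 and 103 RPM at high N, and 24.5 and 2.83 RPM at low N. miR528, which targets copper proteins, had 7.33 and 28.7 RPM at high N, and 39.1 and 17.3 RPM at low N. The abundant miR159 (2418 and 1713 RPM, then 2421 and 4628 RPM) and miR319 (1708 and 1438 RPM, then 721 and 1294 RPM) differed less. The first-base dependence of the ear ratios given above applies to these values.

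**Figure D4:**
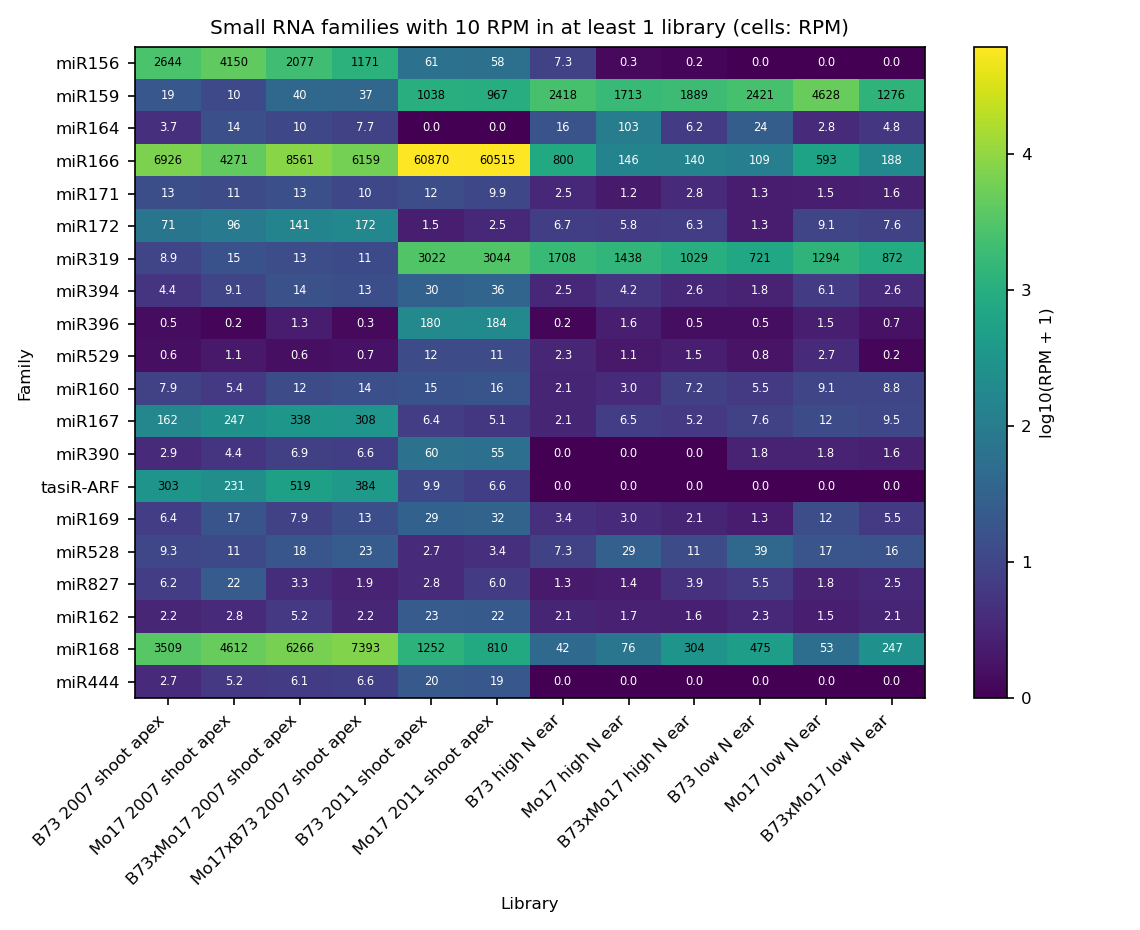
RPM of each small RNA family (rows) in each of 12 libraries (columns), coloured by log10(RPM + 1), for families with at least 10 RPM in 1 library. miR166 and miR168 lead in the 2007 apex, miR166 and miR319 in the 2011 apex (60870 and 3022 RPM in B73), and miR159 and miR319 in the ears.

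Against the mid-parent, 6 families could be tested in the 3 experiments with B73xMo17, and none passed. The means were −1.40 for miR164, 0.96 for miR168, −0.68 for miR166, −0.25 for miR319, −0.21 for miR528 and −0.08 for miR159 on the log2 scale (SE 0.69 each). Leaving out 1 experiment gave means from −2.21 to −0.57 for miR164, 0.27 to 1.49 for miR168, −1.32 to −0.14 for miR166, −0.41 to −0.07 for miR319, −0.70 to 0.08 for miR528 and −0.80 to 0.62 for miR159. The smallest limma adjusted p was 0.387, for miR164, with 0 at an unadjusted p under 0.05. In the 2007 apex 12 of 15 families lay above the mid-parent in B73xMo17 and 10 of 15 in Mo17xB73. All listed sequences that match both genomes summed to 127.6 and 137.9% of the mid-parent in these hybrids, so a place above it is not particular to families, and miR164, miR171 and miR319 (0.21, 0.14 and 0.07 on the log2 scale) in B73xMo17 were near 0. The 3 families of the auxin list that could be measured also lay above it in both hybrids, without a correction for that general shift: miR167 (338 and 308 RPM against 162 RPM in B73 and 247 RPM in Mo17), tasiR-ARF (519 and 384 RPM against 303 and 231 RPM) and miR160 (12.2 and 13.8 RPM against 7.87 and 5.38 RPM), all of which target auxin response factors. miR168 had 6266 RPM in B73xMo17 and 7393 RPM in Mo17xB73. miR172 had 141 and 172 RPM. miR156 lay below both parents in both hybrids (2077 and 1171 RPM), as did miR827 (3.28 and 1.87 RPM). These 2007 values have no replicate.

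High and low N were compared within each genotype, without a test, since the tables differ in library and filter. Of 5 families with 10 RPM in an ear of each genotype, 0 were 2-fold apart in one direction in all 3 genotypes, and 1 (miR319, −1.24 in B73, −0.15 in Mo17 and −0.24 in B73xMo17, log2 of low over high N) kept one direction, where chance gives 1.25. miR166 stood at −2.86 in B73, 2.02 in Mo17 and 0.43 in the hybrid, and miR168 at 3.47, −0.52 and −0.30. The RPM sum of the 24-nt class was higher at low N in all 3 genotypes, with log2 ratios of 0.08, 0.32 and 0.16, and so was that of the 21-nt class, with 0.08, 0.26 and 0.30. These were 2 of 9 length classes, where chance gives 25%, and the others went both ways.

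Between tissues only levels are given. miR156 had 1171 to 4150 RPM in the 2007 apex, 57.7 and 61.1 RPM in the 2011 apex and at most 7.33 RPM in the ears. tasiR-ARF had 231 to 519 RPM, 6.63 and 9.88 RPM, and had no listed member in the ears. miR159 had 10.3 to 39.5 RPM in 2007 but 967 and 1038 RPM in 2011, and miR396, which targets growth-regulating factors, had 0.16 to 1.29 RPM and 180.4 and 184 RPM. Seedling age, year and library kit differed between the shoot apex experiments. All 28 families together held 13.6 to 17.4% of the listed RPM in 2007, 21.4 and 22.5% in 2011 and 1.42 to 3.57% in the ears.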

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

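Several values stood out because the difference between genotypes was not alike in ears and shoot apices. None of these differences was tested, and the rule was applied after the values were computed. The B73 minus Mo17 difference of the 23-nt share was 0.708 points higher in the ears than in the shoot apices. For the hybrid against the mid-parent, the 23-nt share stood −1.26 points lower in the ears and the 24-nt share 4.51 points higher, which rests on the high N ear (6.996 points, against 0.117 at low N) and on 2 apex hybrids of 1 experiment with 1 shared mid-parent. The mean log2 ratio of hybrid to mid-parent was lower in the ears by −2.11 for miR159, −1.70 for miR166 and −1.67 for miR528. The apex side of these family values is again the 2 hybrids of 2007 with their shared mid-parent. There all listed sequences that match both genomes summed to 127.6 and 137.9% of the mid-parent, and to less in both ears. The family values were not corrected for this general shift. In 2007 miR159 had 10.3 to 39.5 RPM and miR528 9.26 to 23.4 RPM, with at least 1 inbred near the 10 RPM minimum.

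A second pattern was data in the low N table that no planned comparison used. Some columns without a header give a class name for 230 sequences, all of which match only Mo17. The 161 sequences named Retrotransposons had 386 RPM in Mo17, 79.7 RPM in B73 and 208 RPM in B73xMo17. This difference was not tested, since the columns cover 0.183% of the table.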

How the results depend on the processing

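Every alternative below was fixed beforehand except the choice of sequences in the other experiment, the 5 RPM minimum for one-genome sequences and edgeR, which were chosen after the results were seen. With 1 library per group, the alternatives vary the treatment of the same libraries and cannot replace replicates. The cause of the changes was not tested, except where construction shows it. The planned restriction to single perfect matches was not run, since it needs a genome.

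As a log2 ratio of class RPM, B73 over Mo17 was 0.21 (24 nt) and 0.42 (22 nt), above 0 in 4 of 4 experiments for both (exact p = 0.125). The listed RPM of 18 to 26 nt was itself higher in B73 in 4 of 4 experiments, and this measure includes that difference. It was 85454 against 77914 in 2007, 300255 against 281442 in 2011, 203749 against 174514 at high N and 205097 against 185085 at low N. Only sequences with a perfect match are listed, so Mo17 sequences missing from the clones and the B73 genome would lower the Mo17 sums. This was not tested. With only sequences at or above 5 RPM the 22-nt mean was 5.74 points. Shares changed sign in 3 cases. Counting distinct sequences, the 24-nt share of B73 minus Mo17 was −0.0292 points and the 22-nt share of hybrid minus mid-parent 0.379 points. Without the high N ear, the 24-nt share of hybrid minus mid-parent was −0.567 points. Over leave-one-out it ranged from −0.567 to 3.56, the 22-nt share of the hybrid from −1.52 to −1.01, and B73 minus Mo17 from 1.02 to 4.27 (24 nt), 1.78 to 3.65 (22 nt) and −1.91 to −1.25 (21 nt).

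The percent of sequences apart between the inbreds at 4-fold, with a minimum of 50 RPM and with 5 RPM added was 35.7, 23.3 and 44.1 in 2007, 36.4, 39.1 and 41.4 in 2011, 80.5, 90.1 and 87.6 at high N, and 66.1, 84.2 and 75.4 at low N. A 4-fold limit lowers it by construction. For the reciprocal hybrids it was 0 at 4-fold and 0 with 5 RPM added.

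The percent of sequences with the hybrid between its parents at 4-fold, at 50 RPM, with 5 RPM added and with sequences chosen in the other experiment of the tissue was 97.0, 85.7, 93.8 and 60.6 for B73xMo17 in 2007, 80.7, 70.6, 77.4 and 40.8 at high N, and 85.1, 74.9, 80.8 and 47.1 at low N. For Mo17xB73 it was 94.0 at 4-fold, 78.6 at 50 RPM and 57.5 with the other experiment. Choosing in the same table favours a hybrid between the parents by construction. The choice in the other experiment also dropped the 2-fold and 10 RPM limits where the hybrid was read. Its lower values therefore cannot be put down to the choice of sequences alone.

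With a minimum of 50 RPM, the percent of B73 sequences listed in the hybrid was 90.5 at high N and 97.7 at low N. With at least 5 RPM in the inbred, Mo17-only sequences held 59.9% (B73xMo17) and 66.4% (Mo17xB73) of their inbred level in 2007 and 21.3% at low N, and B73-only sequences 19.5% at high N and 24.4% at low N.

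Calls between the inbreds were 1 with a minimum of 20 RPM (25 tested), 438 with no minimum (1865 tested) and 19 to 73 over leave-one-out, where more sequences reached the minimum. The hybrid comparison had 2 calls with a geometric mid-parent, 54 with edgeR and library totals and 51 with edgeR and TMM, and 0 in every leave-one-out. The edgeR contrast uses a geometric mid-parent by construction, which is never above the arithmetic one and so favours calls above it. It was not run with an arithmetic one, so the rest of the gap to limma was not tested. The family comparisons had 0 calls in every leave-one-out.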

Other observations

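In the high N ear the start of 5.8S rRNA differed between libraries. Fragments that start GACACGACTCTC made up 94.7% of the 5.8S fragments in B73, 15.5% in Mo17 and 55.2% in B73xMo17, while those 1 base longer, CGACACGACTCTC, made up 1.50, 75.8 and 26.5%. In the low N ear the inbreds were the other way round, with 27.3% GACACGACTCTC in B73 and 55.6% in Mo17, and 36.9 and 16.996% CGACACGACTCTC. In 2007 the inbreds had 28.6 and 16.4% GACACGACTCTC, and in 2011 17.2 and 17.1%. In the same 2011 table, 76.9% of B73-only sequences with at least 10 RPM in B73 were above 0 in Mo17, and 92.2% of such Mo17-only sequences were above 0 in B73, against 4.20 to 19.4% in the other tables, whose depth is lower. The labels give both 2011 libraries the same barcode. Neither depth nor barcode was tested here.

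The opposite microRNA ratios of the inbreds at high and low N were examined with a test predicted beforehand and a test of barcodes chosen after the ratios were seen. A bias of the ear libraries at the 5' end was predicted beforehand to explain over 10% of the variance by the first 3 bases in both ear tables. It explained 49.6% at high N but 7.33% at low N, so this account cannot be told apart from others. miR166 and miR168 both start with TCG and had opposite ratios, so the first 3 bases alone are not the whole account. For the last base of the barcode, over 64 groups of first 3 bases, ear libraries with the same last base correlated at −0.114 and −0.135, a negative result. Centring each sequence over the 6 libraries pulls such correlations below 0. Longer 5' sequence, a genotype difference and a genotype by nitrogen effect were not tested.

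B73-only sequences with abundance in Mo17 were tested with predictions written beforehand. Cross-contamination would leave low ratios, but at most 4.53% of the Mo17 RPM of these sequences lay in sequences under 0.1 of the B73 level. At least 89.1% lay in sequences over 0.5 of it, which is consistent with sequences missing from the Mo17 shotgun clones. For Mo17-only sequences in B73 the highest share under 0.1 was 6.57%, in 2011. These shares are weighted by RPM in the other inbred, so sequences with a low ratio could add little to them. In 2007 1 read was 0.163 RPM in Mo17, so sequences of low B73 level could not have a ratio above 0 and under 0.1. The test therefore cannot exclude a low level of transfer between libraries.

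Mo17-only sequences held more of their inbred level in hybrids than B73-only sequences in 2007 and at high N, but not clearly at low N, where the quotient was 1.04, and 0.874 with at least 5 RPM in the inbred. Length classes differed: at low N the 22-nt quotient was 2.12 (2.44 with that minimum), and at high N the 21-nt quotient was 0.583 (0.329 with it). A maternal effect, tested after the values were seen, would give a quotient under 1 in B73xMo17 of 2007, where it was 1.68, with 1.66 in Mo17xB73. The deposit minimum and unequal depth, predicted beforehand, may account for the summed 2007 values, whose quotients were 1.01 and 1.02 with at least 5 RPM in the inbred, but for 22-nt sequences of 2007 that minimum did not lower the quotients (1.35 and 1.34 without it, 1.39 and 1.41 with it) and the high N quotient was 2.29, so this explanation cannot be told apart from others.

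Other assignments of the libraries were counted as planned. For the inbreds, 1 of 8 splits gave as many calls as the real one (11, highest other 0), and 8 splits are too few for a share under 0.05. For the hybrid, all 27 of 27 choices of the library called hybrid gave at least the real count of 0, which any data would meet, so this count says nothing. The highest other was 67, with Mo17 taken as the hybrid in each table.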
